A study of Drosophila melanogaster with 4 samples.

How the data were processed

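The 3' ends of polyadenylated RNA were sequenced from Drosophila melanogaster testes with the Lexogen QuantSeq forward kit. This kit primes on the poly(A) tail and reads toward it, so that reads lie near transcript 3' ends. Per the labels, RNA came from 150 pairs of testes per sample, and 2 libraries carried the bam-GAL4 driver alone (control) while 2 carried the driver with an RNAi construct against kmg (Kmg knockdown). The labels gave 4 samples in 2 groups. Crosses were held at 25 °C for 3 days before eggs and early larvae were moved to 29 °C, and males were 0 to 2 days old at dissection, per the labels' protocols.

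The submitters' processing notes name STAR 2.7.11b and bedtools and the genome builds dm6 and BDGP6. The clustering program is not given in the sources used here. The authors deposited a table of 3' end clusters for each genotype and a table of consensus clusters over both genotypes. The deposited values were read as raw counts of tags per cluster: they are whole numbers whose sums differ between genotypes and far exceed 1000000, although the file headers call the column TPM. Other deposited columns used are the width of a cluster in bp and its number of tagged positions, per the file headers. Each genotype had 1 value per cluster. How the 2 libraries of a genotype were combined is not recorded in the labels or headers. The totals were 82975478 tags for the control and 87610940 for the pool labelled knockdown. Thus 1 tag was worth 0.0121 and 0.0114 tags per 1000000. The lowest total of a consensus cluster was 50 tags, and single-position clusters had 50 tags or more, so a cluster absent from a table is not a count of 0. Where the control had no cluster, the tags of the other pool are given without a fold.

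Tag counts were divided by the genotype's total and given as counts per 1000000 tags (CPM). The gene table used gives bounds of genes on dm6 (Release 6) without strand, exons or sequence; genes of small RNA classes and those off the main chromosome arms were left out. Strand was therefore inferred from the tags near gene ends, in windows of 100, 200 and then 500 bp, where at least 50 tags lay near the 2 ends together and 90% of them were on the strand that fits one end. A call was dropped where the other strand held more tags within the gene and outside other genes. This oriented 12136 of 16806 genes, among them 10743 of 13946 protein-coding genes. Of 8943 genes that could be oriented from each genotype alone, 99.4% had the same strand. A gene's value was the sum of the sense clusters inside it or up to 500 bp past its end, by the cluster's strongest position. Unlisted clusters added no tags to this sum, so folds can be too high where fewer control clusters were listed. Clusters in several genes went to coding before noncoding genes and then to the nearest gene end. Counts of tags on either strand, given as an alternative, took all clusters within gene bounds. They had no window past the gene end, and a cluster in several genes was counted in each. They therefore differ from the main values in more than the strand. Position classes were drawn from gene bounds. Classes by UTR, exon or intron, distances from stop codons and a filter on genomic A-rich stretches, all planned, were not analysed here because they need exons or sequence. 3' end choice was therefore measured over all sense sites of a gene rather than over its last exon.

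With 1 value per genotype no test between genotypes was possible. No p-value or standard deviation is given, and the planned replicate-based tests were not run. Sizes were called by a fixed rule: 4-fold or more apart on the log2(CPM + 1) scale, with 10 CPM or more in the higher genotype. Intervals are 95%: exact binomial (Clopper-Pearson) for ratios of tags, Wilson for shares and order statistics for medians of gene lists. Those on tags cover counting error only, since no molecular identifiers are recorded. In the list analysis genes needed 1 CPM in the higher genotype, and each list's median was placed among 10000 random lists of the same size matched on mean level in 20 bins. This percentile describes these pools and is no test. For 3' end choice, genes needed 10 CPM in both genotypes and at least 2 consensus clusters with 10% or more of the gene in a genotype, and a change of the distal-most share by 20 percentage points was counted.

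The rule for the genes named was fixed before the data were examined, as were 18 gene lists and most alternatives. It took kmg and its partners, the 12 largest changes per direction, the member with the highest mean and the 3 largest changes of each list with at least 3 measured members, the 5 largest changes of 3' end choice per direction, and the 5 strongest clusters outside genes in each genotype. A selection of these is named in the text. DnaJ-H, ninaE, Arr2 and the members of gene families named in the closing section were chosen after their values were seen. 11 list names were matched through the synonyms of the gene table, and mnm and scpr were left unmatched in the lists.

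Alternatives were other pseudocounts, minimum levels, downstream windows, overlap rules, consensus clusters, and scaling by the median gene, by edgeR 4.0.16 TMM factors or by DESeq2 1.42.0 size factors (R 4.3.3). Only the factors of these tools were used. Each scaling was subtracted from the log2(CPM + 1) changes, and the 10 CPM minimum was left unscaled. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data: tags were drawn from the real clusters' mean levels, with 200 genes changed. For the gene-level comparison, none of the 50 genes simulated at 3-fold and 100% of the 50 each at 6-, 10- and 20-fold passed the 4-fold rule, and 0 of 6958 unchanged genes did. For 3' end choice, 97.0% of 100 genes moved by 40 points were counted. These simulations hold no variation between animals or libraries.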

Results

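3' end sequencing compared testes of control males, which carried the germline driver bam-GAL4 alone, with testes of males in which the same driver expressed RNAi against kmg, a zinc-finger gene of spermatocytes. The series asks, by its title, about repression of cryptic promoters in a differentiating adult lineage. The control pool held 82975478 tags in 50037 clusters and the pool labelled knockdown held 87610940 tags in 67895 clusters. Each genotype was labelled with 2 libraries but had 1 value per cluster, so no difference below has a replicate check. Intervals on tags cover counting error only, and those of medians cover the spread among genes.

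The direction of the targeted gene rested on the scaling. kmg (2L:13160527-13163153, dm6, strand inferred as +) had 288 tags in the control and 446 in the pool labelled knockdown, in the 1 cluster assigned to it, at its annotated end (13163101-13163190). This was 3.47 against 5.09 CPM, a ratio of 1.47 (95% interval 1.26 to 1.71). A cluster of 64 tags near the start of kmg (13160580-13160591), listed in the pool labelled knockdown and not in the control, was assigned to the upstream gene Pk34A. All listed sense tags within kmg and 500 bp past its end were 288 and 510. No ratio is given for these, since the control may hold unlisted tags at the 64-tag cluster. By the assigned cluster, the ratio was 1.06 (0.914 to 1.24) after centring on the median gene, 0.757 (0.651 to 0.881) with TMM factors, 0.670 (0.577 to 0.780) with DESeq2 size factors and 1.23 (1.05 to 1.43) over the tags outside the 50 top control genes. The pool is therefore called "labelled knockdown" throughout, and every direction below rests on that label. DnaJ-H, the convergent neighbour of kmg, chosen after its values were seen, had 0.496 times the control's CPM on its own strand (0.487 to 0.506). simj, named beforehand among the kmg partners, was 5.94-fold higher in the pool labelled knockdown (5.69 to 6.20). The strand of Mi-2, a chromatin remodeller, could not be inferred, and its ratio was 1.47 on the - strand and 1.16 on the + strand. No listed cluster was assigned to MEP-1, although its strand was inferred from tags near its end, so this is not an absence of tags. With tags on either strand within gene bounds, which can belong to overlapping genes, all 4 of kmg and its partners were measured. Of these, 3, kmg among them, were 2-fold or more higher in the pool labelled knockdown and 1 was within 2-fold. This count has no downstream window, so it left out the end cluster of kmg. For kmg it took in antisense tags and the 64-tag cluster not listed in the control, so it is no measure of kmg.

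**Figure D1:**
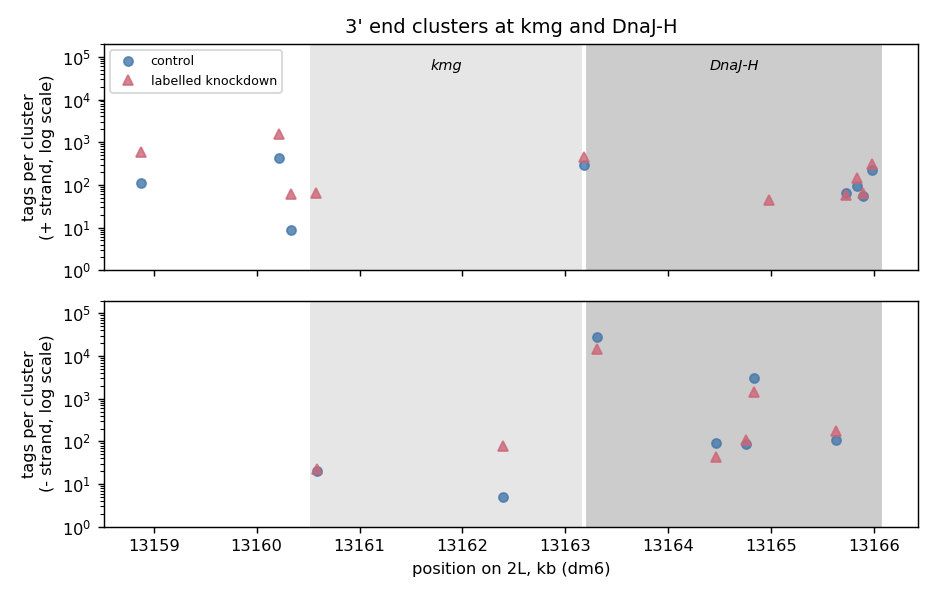
Clusters of 3' ends around kmg and DnaJ-H, with position on 2L in kb (x) and tags per cluster on a log scale (y), the + strand above and the - strand below, circles for the control pool and triangles for the pool labelled knockdown. The cluster at the end of kmg has 288 and 446 tags, and the main DnaJ-H cluster on the other strand has 27439 and 14324.

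Transcript levels differed in a way that followed abundance. Among genes with a mean of 1000 CPM or more the median log2 change was -0.84 (92 genes, interval -1.04 to -0.65), between 100 and 300 CPM it was 0.02 (1236 genes, -0.06 to 0.10), and between 10 and 30 CPM it was 1.60 (2819 genes, 1.53 to 1.66). The 50 genes with most control tags held 28.3% of the control's tags and 14.2% in the pool labelled knockdown, and 47 of these 50 were lower there. Of 8146 genes at 10 CPM or more in either pool, 2216 were 4-fold or more higher in the pool labelled knockdown and 351 were lower. At 2-fold these numbers were 4269 and 887. The balance depended on the scaling: higher genes were 86.3% of those 4-fold apart by CPM, 73.7% after centring on the median of the 5040 genes at 10 CPM in both (1516 higher, 540 lower), 53.8% with TMM factors (995 and 853) and 46.2% with DESeq2 size factors (872 and 1016). Over the tags outside the 50 top control genes it was 80.1% (1797 and 447). Median centring, TMM and DESeq2 subtract 0.47, 0.95 and 1.13 from every log2 change below, so a positive change by CPM of less than 1.13 turned negative under at least 1 of them. The subtraction came after the pseudocount. At low levels it gives a lower change than rescaling the levels first, so the numbers under these scalings lean towards lower genes.

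**Figure D2:**
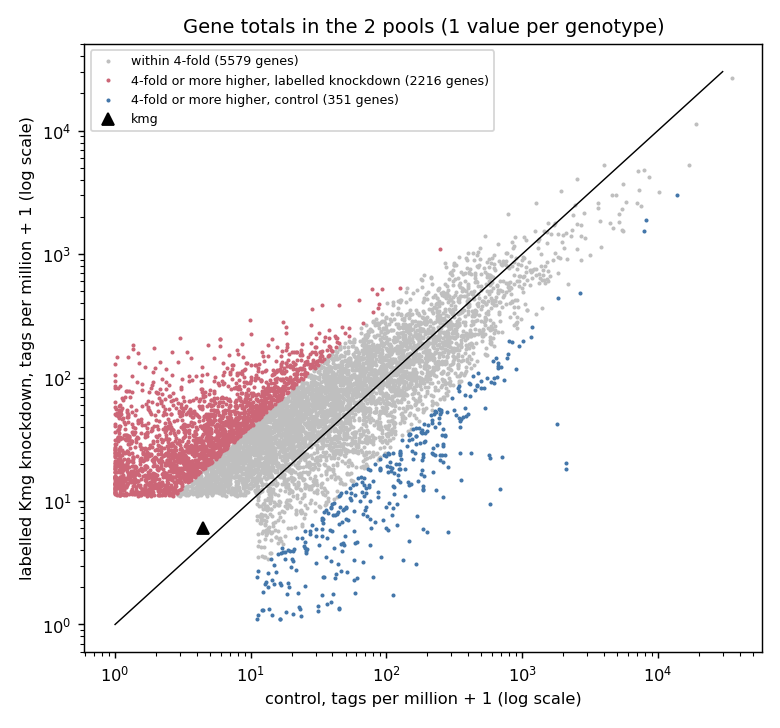
Each point is 1 gene at 10 CPM or more in either pool, with control (x) and labelled knockdown (y) as CPM + 1 on log scales; the line marks equality and the triangle marks kmg. Red points are the 2216 genes 4-fold or more higher in the pool labelled knockdown, blue points the 351 lower ones, and most red points lie at low control levels.

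The named genes furthest above the control had few tags there. Osi22 (3R:13290629-13291846), of the Osiris family of insect cuticle-forming epithelia, had 3 tags in the control and 12736 in the pool labelled knockdown, a ratio of 4021 (1376 to 19499). It had 1 listed control cluster against 6 in the other pool, so unlisted control tags could lower this fold. Cpr64Ab (3L:4210880-4211540), which encodes a cuticle protein, was 571-fold higher (374 to 923), and the uncharacterised genes CG18493 and CG13724 were 520-fold (362 to 777) and 468-fold higher (328 to 694). CG16815 had no control cluster and 9134 tags in the pool labelled knockdown, and CG6296 had none and 7069 tags; no fold is given for these. Over all 2216 higher genes the median level was 2.94 CPM in the control and 32.3 CPM in the pool labelled knockdown. 66 of them had no control cluster assigned, and 555 were under 1 CPM in the control. Assignment can leave a gene without control tags: the 66 include gdl, which shares its clusters with gdl-ORF39. They also include asRNA:CR42871, with 1567 control tags by consensus clusters.

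The genes furthest below the control included testis and male-specific genes. The neighbouring paralogs scpr-A, scpr-B and scpr-C, of a family of secreted cysteine-rich proteins, had 2087, 2103 and 1816 CPM in the control and 17.1, 19.1 and 41.0 CPM in the pool labelled knockdown. They were 122-fold (116 to 129), 110-fold (105 to 115) and 44.3-fold lower (42.8 to 45.8), and how reads were shared among these paralogs is not given in the sources used here. Prosbeta5R1, a testis-specific proteasome subunit, was 77.8-fold lower (67.2 to 90.4), and CG31415 was 60.4-fold lower (56.7 to 64.3). Mst57Db, a male-specific transcript, was 151-fold lower (118 to 196). gdl and gdl-ORF39 overlap and share all their clusters, so each one's value depends on assignment; together they had 582 CPM in the control and 135 CPM in the pool labelled knockdown, 4.31-fold lower (4.22 to 4.39).

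List medians of regulators of the spermatocyte program and of later sperm differentiation differed in direction under every scaling tried, although by CPM most genes of the later lists were within 2-fold. Of 13 tMAC and testis TAF genes, the transcription machinery of spermatocytes, 11 were 2-fold or more higher in the pool labelled knockdown, with a median log2 change of 1.70 (1.16 to 1.91) at percentile 93.4 of matched lists. Those matched lists had a median of 1.02. topi was 4.94-fold (4.66 to 5.23), achi 4.68-fold (4.41 to 4.96) and Taf12L 3.77-fold higher (3.69 to 3.84). Of 27 spermatid differentiation genes 9 were 2-fold or more lower, 1 higher and 17 within 2-fold, with a median of -0.83 (-1.02 to -0.46) at percentile 0.655. Lists matched to them on level had a median of -0.20. By CPM, level alone thus gave the tMAC and spermatid lists opposite signs, and both observed medians were larger in size. Mst87F, which encodes a sperm tail protein and held 714706 control tags, was 2.06-fold lower (2.05 to 2.07) and Mst84Db 4.31-fold lower (4.28 to 4.33); the Mst84D genes are close paralogs. Genes transcribed after meiosis (cups and comets) had a median of -0.59 over 16 genes (-2.36 to 0.11, percentile 0.910), of which 11 were within 2-fold and 5 lower, with schuy 7.89-fold (7.63 to 8.15) and sunz 6.19-fold lower (5.87 to 6.52) and soti 1.31-fold lower (1.30 to 1.33). This list named scpr, which was left unmatched, so scpr-A, scpr-B and scpr-C are not counted in it. The 16 measured spermatocyte and meiosis genes, which count gdl as strongly higher by assignment, had a median of 1.40 (-0.24 to 2.84, percentile 98.7). Without gdl the median was 1.23 over 15 genes (-0.24 to 2.39, percentile 93.9). Tags on either strand within gene bounds gave 0.37 over 19 genes (percentile 56.5), with 9 higher and 3 lower by 2-fold or more. Among them mod(mdg4) had 10.5 CPM in the control and 128 CPM in the pool labelled knockdown, and fest, the most abundant, was 1.15-fold lower (1.14 to 1.15). 8 Y-linked fertility genes had a median of -0.31 (-1.05 to 3.97, percentile 0.150), and 6 of them were within 2-fold. Pp1-Y1 had no control cluster and 1281 tags in the pool labelled knockdown, while Pp1-Y2 was at 21.8 and 42.6 CPM. ORY, whose strongest site lay at -53496 bp from its annotated end, was 2.22-fold lower (2.02 to 2.44). Accessory gland genes, described with the other tissues, were lower in the same pool as the spermatid genes.

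All 12 measured early germline genes were 2-fold or more higher in the pool labelled knockdown, with a median log2 change of 2.28 (1.48 to 2.79) at percentile 95.1. Counting both strands within gene bounds, without the downstream window, gave 1.28 over 15 genes, at percentile 45.1. Of these genes, 9 were higher by 2-fold or more and 6 were within 2-fold. qin, of the piRNA pathway, was 33.3-fold (25.1 to 45.0), zpg, a germline gap junction gene, 28.0-fold (19.7 to 41.2) and vas, a germline RNA helicase, 9.87-fold higher (8.42 to 11.6). These were low in the control, where qin had 50 tags and zpg had 32, and the strongest site of qin lay at -53473 bp from its annotated end. Of 12 genes of somatic testis cells 7 were 2-fold or more higher, with a median of 1.39 (0.33 to 1.92) near that of matched lists (percentile 43.8). so was 5.04-fold higher (4.79 to 5.31), while Stat92E had 27.0 CPM in the control and 103 CPM in the pool labelled knockdown. Fas3, whose strongest site lay at -72872 bp from its annotated end, was 1.71-fold lower (1.65 to 1.78).

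Genes of other tissues did not move as a block. Photoreceptor genes had a median log2 change of 3.33 over 12 genes (0.45 to 4.83, percentile 99.99), and 8 were 4-fold or more higher in the pool labelled knockdown. Counting both strands within gene bounds over 17 genes gave 1.22 (percentile 73.7). inaD, a scaffold of the visual cascade, had no control cluster and 4367 tags in the other pool. ninaC was 41.1-fold higher (35.8 to 47.5), and inaC had 2 and 2465 tags, a ratio of 1167 (323 to 9644). Of genes chosen after their values were seen, the rhodopsin gene ninaE had 21 and 2078 tags, and no cluster was listed at Arr2 in either pool. rdgB, the most abundant of the list, with its strongest site at -11672 bp from its annotated end, was 2.35-fold lower (2.30 to 2.40). Of 9 neuronal genes 6 were 2-fold or more higher (median 1.59, 0.62 to 4.09, percentile 49.0), among them Gad1, the GABA-synthesising enzyme, 107-fold (68.6 to 179) and Nlg2 44.1-fold (33.2 to 59.8). Gad1 had 1 listed control cluster against 6 in the other pool and Nlg2 6 against 10, so unlisted control tags could lower these folds. Only 9 of the 32 neuronal genes could be oriented. Over 31 genes with both strands counted within gene bounds the median was 0.86, below most matched lists (percentile 3.98). Gut and salivary gland genes had a median of 2.03 over 8 genes (0.79 to 4.55, percentile 97.2), with Amy-p at 125 and 412 CPM. Mal-A1, a maltase gene, had 3 and 2040 tags, a ratio of 644 (220 to 3126).

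Accessory gland genes were mostly lower in the pool labelled knockdown, and muscle and fat body genes were mixed. The muscle list had a median of -0.51 over 19 genes (-1.08 to 0.23, percentile 0.0200), of which 12 were within 2-fold, 5 lower and 2 higher, with Act87E 2.83-fold lower (2.75 to 2.90). Accessory gland and duct genes had a median of -1.34 over 19 genes (-2.43 to -0.04), below all 10000 matched lists, and 12 were 2-fold or more lower and 2 higher. Acp98AB was 71.5-fold (56.5 to 91.9) and SP, the sex peptide gene, 94.7-fold lower (59.7 to 160), whereas EbpIII, the most abundant, had 120 and 117 CPM. Fat body and hemocyte genes had a median of -0.70 over 9 genes (-3.09 to 1.30, percentile 0.180), of which 4 were 2-fold or more lower and 2 higher, with Fbp1 72.0-fold lower (53.9 to 98.6) and Apoltp 11.7-fold higher (10.3 to 13.5). Markers of these attached or neighbouring tissues thus differed between pools alongside the germline lists.

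Genes of the cleavage and polyadenylation machinery, which makes the 3' ends measured here, were higher in the pool labelled knockdown in 16 of 17 cases by 2-fold or more, with a median of 1.93 (1.53 to 2.37, percentile 93.9). CstF64 had 7.09 CPM in the control and 154 CPM in the pool labelled knockdown, Pabp2 had 51.7 and 250.5 CPM, and Fip1 was 7.49-fold higher (7.07 to 7.95). The 6 genes with neural 3' UTR extensions had a median of 0.86 (-0.41 to 1.77, percentile 54.8), which turned negative under TMM and DESeq2 scaling. The 81 ribosomal protein genes had a median of 0.65 (0.54 to 0.81), above all matched lists, and 23 were 2-fold or more higher, but this too turned negative under both of those scalings. Common reference genes had a median of 0.38 over 12 genes (-0.16 to 1.12, percentile 88.4), negative under median centring, TMM and DESeq2 scaling, with alphaTub84B 1.55-fold lower (1.54 to 1.56) and His3.3A 2.44-fold higher (2.39 to 2.48).

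**Figure D3:**
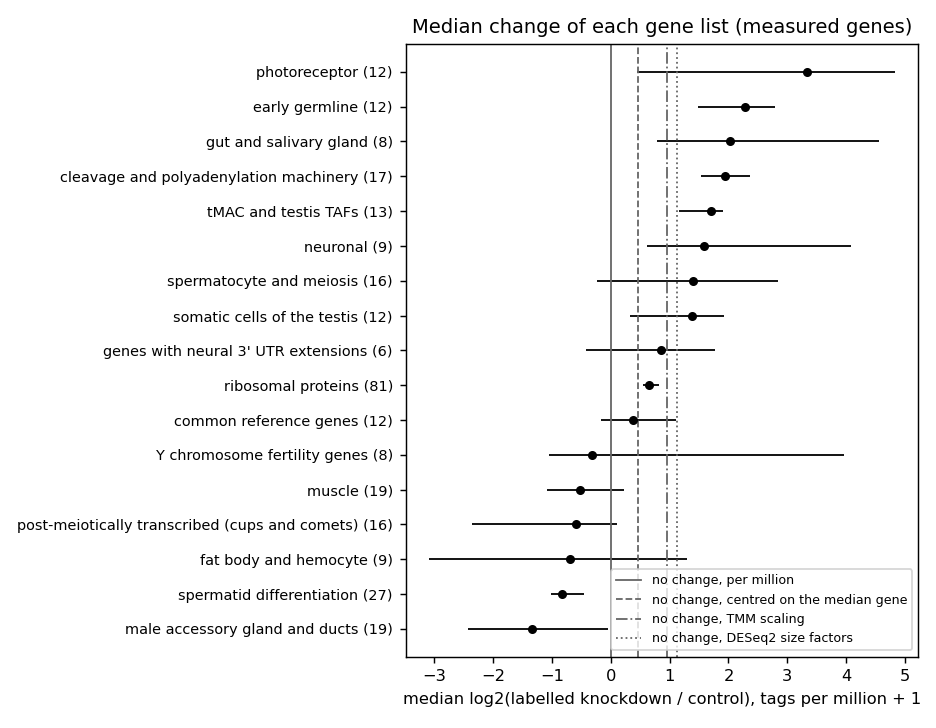
Median log2 ratio of the pool labelled knockdown to the control (x) for each gene list (y, measured genes in brackets), with bars for the 95% order-statistic interval of the median. Vertical lines mark where a median of no change falls under each scaling, at 0, 0.47, 0.95 and 1.13; the spermatid list lies left of all of them and the early germline list right of all, while the ribosomal, reference and neural 3' UTR lists lie between them and change sign.

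The pool labelled knockdown had 1.36 times as many clusters as the control, and 1.62 times as many at 10 CPM or more (11512 against 7116). Tags were less concentrated: the 10 strongest clusters held 13.5% of control tags and 7.37% in the other pool. The median width was 15 and 13 bp. Nearly all control clusters, 98.2%, overlapped a cluster of the pool labelled knockdown, while 71.2% of the latter's clusters overlapped a control cluster. The 19582 clusters found in the pool labelled knockdown alone held 2.76% of its tags, and 276 of them were at 10 CPM or more. The 924 found in the control alone held 0.0746% of its tags, and none reached 10 CPM. When both sets were limited to 10 CPM or more, 87.5% and 54.0% overlapped.

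3' ends outside the sense strand of genes took a larger share in the pool labelled knockdown. Clusters outside genes held 0.516% of control tags (0.514 to 0.518, Wilson) and 2.59% in the pool labelled knockdown (2.58 to 2.59). This class can take in 3' ends just past any of the 4670 genes of unknown strand, which were given no downstream window. Clusters antisense within genes held 0.742% (0.740 to 0.744) and 2.06% (2.06 to 2.07). The last 500 bp of genes held 67.5% and 60.6%, and genes of unknown strand 4.73% and 7.74%. The strongest cluster with no control counterpart (3L:18245130-18245336, - strand) had 9191 tags, or 105 CPM, and lay 908 bp from the noncoding gene lncRNA:CR45936; a second lay beside it (3L:18245448-18245595, 81.1 CPM). Others lay at 2R:13402706-13402898 on the + strand (74.8 CPM, 3481 bp from CG4744), at 2L:3330702-3330908 (68.5 CPM, 224 bp from CG3285) and at 3L:11415547-11415676 (66.5 CPM, 9459 bp from lncRNA:CR44363). Among clusters of the control alone that lay outside genes or antisense, the strongest, at 3L:18546873-18546926, had 7.86 CPM. Priming at genomic A-rich stretches was not assessed here.

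**Figure D4:**
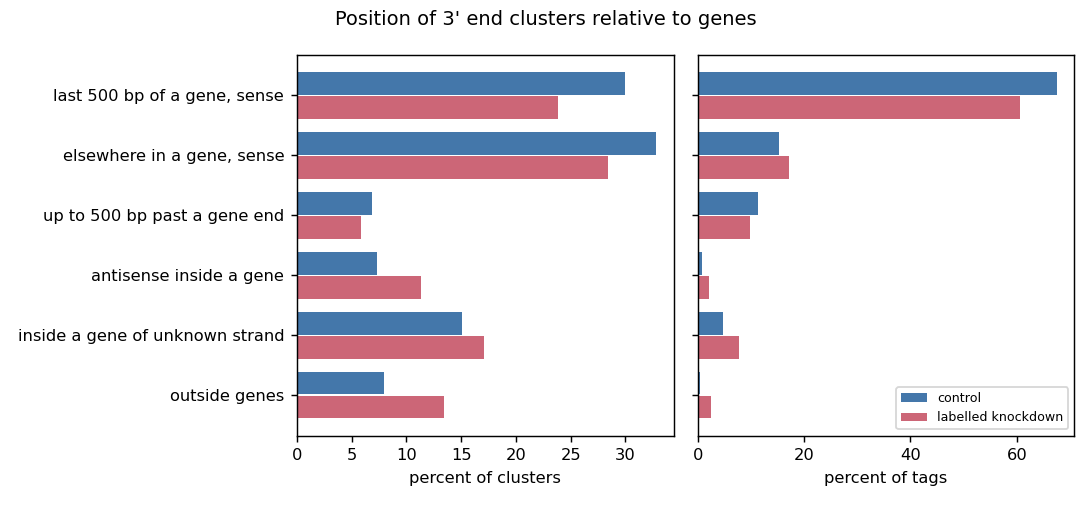
Share of clusters (left) and of tags (right), in percent, by position relative to genes of inferred strand, with blue bars for the control and red bars for the pool labelled knockdown. Positions outside genes, which can include ends just past genes of unknown strand, hold 0.516% and 2.59% of tags. Those antisense within genes hold 0.742% and 2.06%.

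3' end choice was compared by the share of the distal-most site, which does not show shifts among the other sites of a gene. Of 2205 genes with several 3' ends, of which 1335 had exactly 2, this share was 20 points or more higher in the pool labelled knockdown in 153 and lower in 138, together 13.2%, and the median change was 1.45 points. In Tpl94D, a transition protein gene of spermatids, the distal site (3R:22967842, 1093 bp beyond the proximal one) held 0.350% of control tags (0.212 to 0.577) and 85.8% in the pool labelled knockdown (85.2 to 86.4). In Jra, the fly Jun gene, the distal share was 8.11% (7.68 to 8.56) and 76.2% (75.4 to 77.1), and in CG4704 it was 20.7% and 84.9%. In the other direction it was 90.3% (89.4 to 91.1) and 9.12% (7.88 to 10.5) in CG33286, 82.9% and 13.4% in mon2, and 81.7% and 16.7% in TMEM216. The sites of l(3)80Fg (9.82% and 76.7%) lay 185875 bp apart. Without exons, separate transcription units within a gene's bounds were not told from alternative ends of 1 transcript.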

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

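Among the tests reported here, those chosen after the data were seen were the 4 other scalings of kmg, TMM and DESeq2 scaling of the lists, centring on genes with a mean of 10 CPM or more, tags on either strand, stricter orientation, leaving out clusters in several genes, CPM outside the 50 top control genes, the spermatocyte list without gdl, and the spacing or sharing of sites. Of 201 alternatives, 143 left the result within its interval or within 1.5 times its count, 48 moved it and 10 reversed it; for gene lists 108 of 137 left it. Where no cause is named below, the cause was not tested. No paired analysis was possible because each genotype has 1 value and no values per replicate are used here; for that reason the replicate block, edgeR and DESeq2 as tests and leaving out each replicate were not run, and leaving out A-rich clusters was not run because it needs a genome.

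For kmg the log2 change of 0.45 was 0.79 with no downstream extension. That setting by construction leaves out its main cluster and takes in the 64-tag cluster near its start. The control has no cluster listed there and was taken as having no tags, so 0.79 is not a measured change. By the assigned cluster, the log2 change was -0.0199 after centring on the median gene and -0.51 with TMM. It was -0.68 with DESeq2 size factors and 0.19 over the tags outside the 50 top control genes. The value after median centring is negative although the ratio without a pseudocount was 1.06.

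Control clusters shared with the other pool, 98.2% at 1 bp of overlap, were 87.9% at 50% reciprocal overlap, 91.3% with strongest positions within 25 bp, 89.3% among clusters of 3 CPM or more and 87.5% among those of 10 CPM or more. For clusters of the pool labelled knockdown, 71.2% became 64.8%, 67.3%, 52.7% and 54.0%. Tags antisense or outside genes, 1.26% and 4.65%, were 1.20% and 4.52% with a downstream window of 1000 bp and 0.989% and 3.52% among clusters of 3 CPM or more.

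Genes 4-fold higher numbered 1136 with a pseudocount of 5, 995 with TMM, 872 with DESeq2 size factors and 1014 after centring on genes with a mean of 10 CPM or more. Genes 4-fold lower numbered 540 after centring on the median gene, then 853, 1016 and 829 under those 3 scalings. Over the tags outside the 50 top control genes they numbered 1797 and 447. Each scaling shifts all genes by 1 value, which by construction moves these numbers.

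Under TMM the median log2 change was 0.74 for tMAC and testis TAFs, -1.79 for spermatid genes, -1.27 for Y genes, 1.33 for early germline genes, -1.47 for muscle, 0.98 for cleavage and polyadenylation, -0.0925 for neural 3' UTR genes, -0.31 for ribosomal proteins and -0.57 for reference genes. Under DESeq2 size factors the same lists had 0.57, -1.96, -1.44, 1.15, -1.64, 0.80, -0.27, -0.48 and -0.75, and somatic testis, neuronal and accessory gland genes had 0.26, 0.46 and -2.47. Centring on the median gene gave -1.30 for spermatid genes, 1.47 for cleavage and polyadenylation, 0.18 for ribosomal proteins and -0.0835 for reference genes. Early germline genes had 2.86 with a pseudocount of 0.1, 1.37 with 5 and 1.28 with either strand, and cleavage and polyadenylation had 1.52 with a pseudocount of 5. Setting members without tags to 3 tags moved no list's median by more than 0.03.

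3' end choice moved with the genes let in: at 3 CPM or more in both pools the distal share was 20 points higher in 278 and lower in 267 of 3374 genes, and at 30 CPM or more in 65 and 50 of 1184. Depth limits weak 3' ends, since no consensus cluster under 50 tags is listed.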

Other observations

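Which tests were chosen after the result was seen: those of kmg, of share lost by the 50 top control genes and of cluster listing. The tests of diffuse background, of divergent neighbours and of neighbours 1 kb or more apart were set before, but how the last one is read was changed after its result was seen, as was the reading of cluster listing. The 72 gene families with 8 or more measured members were formed from symbols, and those named were picked, after the data were seen. Of 37 ionotropic receptor genes (Ir) 25 were 4-fold or more higher in the pool labelled knockdown, with a median log2 change of 2.76 (2.12 to 3.42), above all matched lists; Ir25a had 10 and 5899 tags. Of 18 Osiris genes 16 were 4-fold or more higher (median 3.13, 2.67 to 4.16), and of 17 pickpocket channel genes (ppk) 11 were (median 2.91, 1.74 to 3.58). Jonah proteases (Jon) had a median of 2.24 over 10 genes (1.49 to 3.80, percentile 99.99). These 10 genes together had 0.109 CPM in the control. Each thus passed the 1 CPM minimum only through the pool labelled knockdown, which fixed a positive change by CPM. The 37 Ir genes together had 21.4 CPM and the 18 Osiris genes 19.2 CPM in the control, so some members could enter the same way. Members under 1 CPM in both pools are not counted. The odorant-binding family (Obp) was not among them, with a median of 0.95 over 31 genes at percentile 6.05 that turned negative under TMM and DESeq2 scaling. Medians of the Ir, Osiris, ppk and Jon families stayed above 0 under TMM scaling, from 1.28 (Jon) to 2.17 (Osiris), and under DESeq2 scaling, from 1.11 to 2.00. At the other extreme, male-specific transcript genes (Mst) had a median of -1.18 over 21 genes (-1.85 to 0.10) and accessory gland genes (Acp) -1.29 over 16 (-2.43 to 0.90), both below all matched lists and partly members of the lists described before. The chaperonin genes (CCT) had a median of 1.59 over 8 genes (1.07 to 2.47, percentile 99.2), 0.64 under TMM and 0.46 under DESeq2 scaling, with CCT8 5.61-fold higher (5.47 to 5.76).

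The X chromosome had lower shares of genes 4-fold apart than 2L and 3L: 19.1% of 1119 genes were higher and 1.07% lower in the pool labelled knockdown, against 26.4% and 5.66% of 1589 genes on 2L and 30.1% and 5.10% of 1646 on 3L. On chromosome 4, 6 of 38 genes were higher and 1 was lower.

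kmg by CPM was not lower in the pool labelled knockdown. Counting error alone does not account for this, since the lower bound of the ratio was 1.26. Share lost by the 50 top control genes is argued against as the whole account, since over the tags outside them the lower bound was 1.05; a loss over more genes stays open, as TMM and DESeq2 scaling shift every gene alike and decide nothing here. Exchanged genotype names cannot be told apart from correct ones here, since 3 of the 6 lists of other tissues had medians above 0 and 3 below; clusters of 1 pool alone (19582 against 924) and tags outside genes (2.59% against 0.516%) run as the labels say only if loss of kmg adds such 3' ends, which these pools cannot show apart from their labels. RNAi that acts in part of the cells, or that leaves 3' fragments, was not tested.

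More genes were 4-fold higher than lower by CPM. Unlisted weak control clusters stay open: 99.4% of the 2216 genes were still 4-fold higher with the consensus totals, but these equal the sum of the listed clusters in 85.3% of cases and hardly add unlisted tags, and the listing rule, which seems to work over both genotypes, is not stated. Diffuse background along genes is argued against: in 1002 higher genes of 3 kb or more, a median of 83.8% (80.2 to 86.2) of the tags in the pool labelled knockdown lay within 500 bp of the annotated end, against 49.8% in 1091 genes within 2-fold and 15.9% for an even spread, although orientation itself needed tags near gene ends. Share lost by the 50 top control genes is argued against as the whole account, since over the tags outside them 1797 genes were higher and 447 lower, a ratio of 4.02. A loss of share over more genes and a gain from the knockdown itself stay open, untested by replicates.

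Neighbouring genes were 4-fold higher together slightly more often than shuffled positions gave, in 682 of 8139 pairs against a median of 611 and a highest of 676 over 10000 shuffles. The shuffles stayed within chromosomes but were not matched on level. By mean level, 1068 of 2819 genes at 10 to 30 CPM were 4-fold higher, against 46 of 1236 at 100 to 300 CPM. An excess over these shuffles therefore cannot be told from neighbours of similar level. Transcription running on into the next gene on the same strand cannot join divergent neighbours. These made 216 pairs against a median of 168 and a highest of 214. Same-strand neighbours made 295 against a median of 276 and a highest of 327, and convergent neighbours 171 against 168 and 210. Tags of one 3' end could not be counted for both genes, since each cluster was assigned to 1 gene, so the test on neighbours 1 kb or more apart decides nothing: they made 347 pairs against a median of 308 and a highest of 362, a ratio of 1.13 to the median against 1.12 for all pairs. A shared regulatory region of divergent genes is a hypothesis that was not tested. Divergent pairs were 1.29 times their shuffled median but passed the highest shuffle by only 2 pairs.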
